A study of Mus musculus with 9 samples.

How the data were processed

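RNA was measured in dissected skin tumors of C57BL/6J mice that carried subcutaneous YUMMER1.7 melanoma cells. The 9 libraries fall into 3 treatment groups of 3: an IgG isotype control, an anti-B7-H3 antibody and an anti-PD1 antibody. The labels give total RNA, depleted of ribosomal RNA before library construction. No label says what the replicate numbers 1 to 3 share, or states that each library comes from its own mouse, so the p-values measure only the spread between these samples. A combination of both antibodies, which the series describes, is not among the libraries.

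Per the file headers, each library has a deposited table of estimated counts (expected read counts per transcript, not normalized), together with TPM values that the authors scaled by effective transcript length, and the effective length itself. The quantifier is not given in the sources used here. The submitters name FastQC 0.11.8 and the GRCm38 build. Of the 58083 transcripts listed, 57409 were matched by identifier to GENCODE M21, and the 674 others held between 0.105% and 0.369% of the estimated reads. The listed length equals the annotated coding sequence for 92.2% of the 57298 matched transcripts that have one, so lengths here are coding lengths and the values hold no UTRs. Estimated counts were summed over the transcripts of each of 22136 genes and rounded to whole numbers.

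Genes were tested in R 4.3.3 with edgeR 4.0.16. Library scale came from TMM, genes with few reads were removed with filterByExpr and the groups, and 1 robust quasi-likelihood model was fitted to all 9 libraries, with group as the only term. That left 12965 tested genes, and 8623 further genes with reads were not tested. Each pair of groups was compared with the quasi-likelihood F test, and 1 test covered all 3 groups. Adjusted p-values are Benjamini-Hochberg values, with 0.05 as the threshold and no minimum fold. Changes are log2 fold changes with their standard errors, and levels are TMM-scaled CPM with the SD over 3 libraries. The biological coefficient of variation was 28.4%. Because TMM centres on the typical gene, every change is relative to the median gene. Scaling by library totals instead moved the median log2 fold change of all tested genes to 3.37 for anti-B7-H3 against IgG, 3.15 for anti-PD1 against IgG and 0.20 for anti-B7-H3 against anti-PD1.

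Before the data were examined, 31 gene lists were fixed for immune cells, immune pathways, tumor programmes and other tissues of a subcutaneous tumor. The 30 lists with at least 5 tested members were tested with camera in limma 3.58.1, at a preset correlation of 0.01, on voom values, and adjusted over the lists of each comparison. The B cell list had fewer than 5 tested members and was not tested. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run beside it. Where a list count adjusted over the list alone is given, the p-values of its members were adjusted among themselves.

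The genes named were chosen by a rule set before the data were examined. Per comparison it takes the 12 largest rises and the 12 largest falls among genes past the threshold with a symbol, a mean of at least 1 log2 CPM and no overlap between the groups. Where fewer than 5 genes pass, it takes the 10 with the smallest p. It adds the antibody targets and genes of the series title, marker genes of immune subsets, Cdkn2a and Braf, and up to 4 members with the smallest p of each list. A few genes picked by this rule are not reported here and are left out of the counts of changes under the alternatives. Which of these list members the text prints was settled after their values were seen.

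Shared controls were handled by simulating 50 data sets with unchanged groups against the same controls. On simulated counts with known changes, the edgeR test found 3 to 6% of genes changed 1.5-fold, 32.8 to 38.8% of those changed 2-fold and 89.4 to 95.5% of those changed 4-fold. Between 1.1 and 5.3% of its calls there were false. A simulated list of 20 genes raised 1.5-fold was found in each comparison, and 0 of 50 random lists were called. Genes were drawn independently there, so this leaves out the correlation between members of the real lists. Splits of the real libraries that mix the groups called 2 to 19 lists.

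A set of 12 genes was marked as major satellite genes by the 15-base words of their full transcript sequences. In the transcript with the highest share, more than 30% of these words occur in the 234-base consensus of the mouse major satellite repeat. Reads of 1509 olfactory and vomeronasal receptor genes, which are expected to be silent outside chemosensory tissue, served as a measure of background. Both measures were chosen after the libraries had been looked at. Alternatives set in advance were DESeq2 1.42.0, limma-voom with and without quality weights, DESeq2 size factors, library totals, other filters on low counts, only the libraries compared, replicate number as a block, effective length offsets, a table without abundant RNA classes, a stricter threshold, a minimum fold, and each library left out. Alternatives added after seeing the data were GC content offsets, removal of the satellite genes, background subtraction, the receptor signal as a covariate, thinning to equal depth, and further left-out libraries. Permutation tests and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Counting intervals are Wilson intervals for shares and exact Clopper-Pearson intervals for ratios, at 95%, and cover counting error only. No library was left out of the reported values.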

Results

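Bulk RNA was profiled in 9 YUMMER1.7 tumor samples, 3 each from mice given IgG, anti-B7-H3 or anti-PD1. YUMMER1.7 is a mouse melanoma line made more immunogenic by ultraviolet mutagenesis. B7-H3 (gene Cd276) and PD-1 (gene Pdcd1) are immune checkpoint proteins that the antibodies bind. Estimated reads came to 27288766, 27205428 and 13624172 in the 3 IgG libraries, 10105153, 14396756 and 15447583 with anti-B7-H3, and 8627930, 10391624 and 11256181 with anti-PD1.

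The libraries differed widely in reads from major satellite repeats, the tandem DNA repeats beside mouse centromeres. The 12 satellite genes took 90.0% ± 2.70 (SD, n = 3) of gene reads with IgG, 13.3% ± 12.9 with anti-B7-H3 and 24.2% ± 12.4 with anti-PD1. In every IgG library the share was at least 87.0%, and in no antibody library was it above 38.2%. No Wilson interval of a library's share was wider than 0.0649 percentage points. Reads outside the satellite genes came to 2147305, 3533214 and 1218985 with IgG, 7232196, 13598625 and 14404557 with anti-B7-H3, and 5320073, 8314746 and 9578312 with anti-PD1. Olfactory and vomeronasal receptor genes had 2254, 767 and 4969 CPM, counted over the reads outside the satellite genes, in the IgG libraries, 198, 41.3 and 40.4 with anti-B7-H3, and 280, 78.1 and 112 with anti-PD1, and the limits of each Wilson interval lay on average at most 8.27% from the value. Thus satellite share and receptor background separated the IgG libraries from the other 6, and both antibody groups are compared with controls that differ in these measures.

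**Figure D1:**
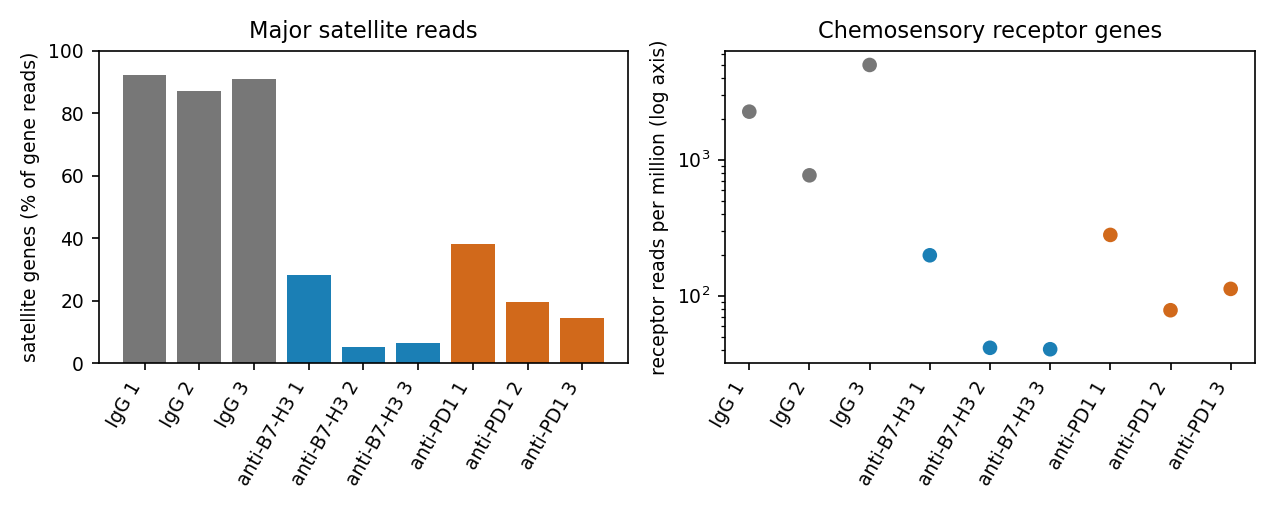
Satellite reads and receptor background in each of the 9 libraries. Bars give the 12 major satellite genes as % of gene reads, and points give olfactory and vomeronasal receptor reads as CPM of the other reads on a log axis, coloured by group. The IgG bars stand at 92.1, 87.0 and 91.0%, and the highest antibody library is anti-PD1 replicate 1 at 38.2%.

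The comparison of anti-B7-H3 with IgG addresses what the antibody changed in the tumor and its immune infiltrate. In camera at the preset correlation, genes of antigen presentation and of phagocytes were higher as groups. Genes of the skin, of red blood cells and of the mitochondrial genome were lower as groups there. With an estimated correlation 0 lists passed. A split that mixed IgG with anti-B7-H3 libraries called 16 lists, against 17 for the real groups. Fc receptor and phagocytosis genes rose, with 21 of 21 members positive and a median log2 fold change of 0.93 (camera adjusted p = 8.9e-09, or adjusted p = 0.411 with an estimated correlation). Of these, 13 passed the threshold adjusted over the list alone, and 0 passed over all genes tested. Members with the smallest p were Lyn, a Src-family kinase, at 1.03 ± 0.27 (SE), and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, at 1.65 ± 0.43. MHC class II presentation genes were positive in 9 of 10 members with a median of 1.19 (camera adjusted p = 3.4e-06, or adjusted p = 0.411 with an estimated correlation), 6 of them past the threshold adjusted over the list alone, and the transactivator Ciita stood at 1.32 ± 0.32. MHC class I presentation genes were positive in 18 of 18 members with a median of 0.76 (camera adjusted p = 3.8e-06, or adjusted p = 0.471 with an estimated correlation). Macrophage and monocyte genes were positive in 21 of 23 with a median of 0.92 (camera adjusted p = 1.0e-05, or adjusted p = 0.445 with an estimated correlation), with Fcgr4 at 1.72 ± 0.60. Checkpoint ligand genes were positive in 13 of 14 with a median of 0.51 (camera adjusted p = 0.0014, or adjusted p = 0.411 with an estimated correlation), 3 of them past the threshold adjusted over the list alone, with Icosl at 1.70 ± 0.50. Without single libraries the medians ran from 0.69 to 1.17 for Fc receptor, 0.90 to 1.64 for MHC class II, 0.46 to 1.35 for MHC class I, 0.46 to 1.18 for macrophage and 0.40 to 0.68 for checkpoint ligand genes. The highest macrophage levels relative to all libraries, 0.98 in both anti-B7-H3 replicate 3 and anti-PD1 replicate 2, stood in the libraries that were also highest for skeletal muscle genes, at 3.53 and 2.90. MHC class I levels overlapped between the groups. They were 0.67, -0.36 and -1.36 with IgG and -0.04, 0.92 and 0.78 with anti-B7-H3.

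Further lists passed the camera test as higher with anti-B7-H3 than with IgG, but their calls rested on single libraries. Interferon gamma response genes had 18 of 20 members positive and a median of 1.05 (camera adjusted p = 2.0e-05, or adjusted p = 0.569 with an estimated correlation). Type I interferon genes had 24 of 24 positive and a median of 0.40 (camera adjusted p = 0.0031, or adjusted p = 0.624 with an estimated correlation). Medians were 0.85 for CD8 T cell and cytotoxic genes (13 of 17 positive), 0.72 for T cell inhibitory receptors (9 of 11), 0.79 for cytokines and chemokines (15 of 18), 0.31 for hypoxia and glycolysis (18 of 21) and 0.22 for fibroblasts and matrix (18 of 20). Their camera adjusted p-values were 0.024, 0.024, 0.014, 0.024 and 0.016 in that order. With an estimated correlation the adjusted p-values were 0.624, 0.445, 0.592, 0.626 and 0.445. Leaving out single libraries gave medians from 0.73 to 1.83 for interferon gamma, 0.01 to 0.93 for type I interferon, 0.30 to 1.38 for CD8, 0.54 to 0.81 for inhibitory receptor, 0.50 to 1.24 for cytokine, 0.18 to 0.58 for hypoxia and 0.03 to 0.48 for fibroblast genes. Each of these 7 calls ended without 1 or more single libraries: without IgG replicate 2 the camera adjusted p-values of interferon gamma, type I interferon, CD8, inhibitory receptor and cytokine genes were 0.129, 0.210, 0.897, 0.576 and 0.353, without IgG replicate 3 those of hypoxia and fibroblasts were 0.262 and 0.296, and without anti-B7-H3 replicate 1 that of fibroblasts was 0.204. Without anti-B7-H3 replicate 2 the inhibitory receptors, type I interferon and hypoxia lists had 0.071, 0.522 and 0.315, without anti-B7-H3 replicate 3 CD8, cytokines and hypoxia had 0.087, 0.064 and 0.442, and without anti-PD1 replicate 2 or 3 the CD8 and inhibitory receptor lists had 0.060 and 0.054. With the receptor signal as a covariate, an alternative added after seeing the data, 0 of the 12 lists stayed called higher, and the medians of MHC class I, cytokines and hypoxia genes turned to -1.02, -0.79 and -0.59 and were called lower.

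Mitochondrially encoded genes were negative with anti-B7-H3 in 13 of 13 members (median -1.07; camera adjusted p = 8.9e-09, or adjusted p = 0.411 with an estimated correlation), 9 of them past the threshold adjusted over the list alone, with mt-Nd2 at -2.29 ± 0.48. Erythroid genes were negative in 6 of 6 (median -2.23; camera adjusted p = 3.4e-06, or adjusted p = 0.327 with an estimated correlation), and the beta globin gene Hbb-bt fell by 2.21 ± 0.42 (edgeR adjusted p = 0.048), a call that held in 6 of 26 alternatives. Keratinocyte genes were negative in 4 of 5 (median -1.18; camera adjusted p = 7.5e-04, or adjusted p = 0.327 with an estimated correlation; fry adjusted p = 0.045), with the desmosome gene Dsp at -4.08 ± 0.79. Melanocyte lineage genes were negative in 5 of 5 (median -0.55; camera adjusted p = 0.016, or adjusted p = 0.411 with an estimated correlation), and Slc24a5, a melanosome cation exchanger, fell by 7.19 ± 0.87 (edgeR adjusted p = 0.0057). Beta-catenin target genes were negative in 10 of 12 (median -0.36; camera adjusted p = 0.020, or adjusted p = 0.411 with an estimated correlation), with Axin2, a feedback inhibitor of the pathway, at -1.14 ± 0.31. Of reads outside the satellite genes, mitochondrial genes took 1.74, 2.09 and 3.32% with IgG and 1.67, 2.40 and 1.64% with anti-B7-H3. Without IgG replicate 3, whose mitochondrial level of 1.53 stood apart from the 0.25 and 0.15 of the other IgG libraries, the mitochondrial median was -0.39, and the list stayed called. Tested members were 5 of 20 listed for keratinocytes, 5 of 17 for melanocytes and 6 of 10 for erythroid cells. A gene can pass the read filter through the IgG libraries alone, so these members may lean toward lower ones. The erythroid and keratinocyte medians ran from -2.66 to -1.30 and from -2.64 to -0.78 without single libraries. Those of melanocyte and beta-catenin target genes ran from -0.69 to -0.28 and from -0.56 to -0.25. Scaled by library totals, these 5 medians are positive, at 2.48, 1.31, 2.21, 2.82 and 3.00, and so is Hbb-bt at 1.32, while the median of all genes is 3.37. Without anti-B7-H3 replicate 1 the melanocyte and beta-catenin lists both had a camera adjusted p of 0.10, without IgG replicate 1 the beta-catenin list had 0.072, and with the receptor signal as a covariate the mitochondrial, melanocyte and beta-catenin lists had 0.401, 0.121 and 0.174. The other 13 lists did not pass, with camera adjusted p-values from 0.055 to 0.986.

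In the main fit, single genes called against IgG were almost all lower. This balance depended on the processing: library totals called 12456 genes higher and 73 lower with anti-B7-H3. Library totals include the satellite reads, on average 90.0% of gene reads with IgG and 13.3% with anti-B7-H3. They put the median change of all tested genes at 3.37. Those 12456 calls are therefore no separate evidence that genes were higher. Quality weights called 152 higher and 280 lower with anti-PD1. With anti-B7-H3, 1 gene was higher and 71 were lower of 12965 tested with edgeR's quasi-likelihood test, against 464 and 898 at an unadjusted p under 0.05. The gene that rose, 9930111J21Rik1 (ENSMUSG00000069893, chromosome 11, 48946150 to 48979398 on GRCm38), had 3.57 ± 1.07 CPM (SD, n = 3) with IgG and 11.25 ± 1.56 with anti-B7-H3, a log2 fold change of 1.66 ± 0.32 (edgeR adjusted p = 0.049). Its call held in 13 of 27 alternatives, where its adjusted p ranged from 5.5e-16 to 1. Gm5148 (ENSMUSG00000058174, chromosome 3, 37714190 to 37724490) went from 21.4 ± 2.32 to 0.211 ± 0.154 CPM, and 1810049J17Rik (chromosome 15, 12321438 to 12321899) from 13.7 ± 6.73 to 0.0884 ± 0.0325 CPM. Their log2 fold changes were -6.80 ± 0.45 and -7.12 ± 0.50 (edgeR adjusted p = 5.1e-05 and 6.0e-05). The mucin genes Muc6, Muc5b and Muc4, whose products coat epithelia, fell, with changes of -9.40 ± 1.38, -6.78 ± 0.95 and -6.61 ± 0.93 (edgeR adjusted p = 0.046, 0.018 and 0.018). Their IgG reads were 4.98, 0.99 and 1.36 times what the receptor background predicts for their coding length, and their calls held in 12 of 27, 19 of 25 and 17 of 26 alternatives. Gm26566 fell by 7.57 ± 0.75 (edgeR adjusted p = 9.6e-04). Gm9573 had 193 reads over the IgG libraries and 2 over the anti-B7-H3 libraries, a 560-fold lower level with a counting interval of 153 to 4660 (edgeR adjusted p = 0.014). Satellite genes made up 11 of the 71, and Gm10719, Gm10718, Gm11168, Gm10720 and Gm10801 lay between -6.25 and -6.17. Satellite genes share words with the same repeat, so how reads divide among them is uncertain.

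How many genes were lower with anti-B7-H3 depended on single libraries. The 71 became 8, 432 and 20 without IgG replicate 1, 2 or 3, 124, 11 and 10 without anti-B7-H3 replicate 1, 2 or 3, and 31 both without anti-PD1 replicate 2 and without anti-PD1 replicate 3. Every call was lost when the receptor signal, which itself sets the IgG libraries apart, entered the model as a covariate, where the median log2 fold change of the 60 lower genes outside the satellites went from -4.71 to -1.05 and its median SE from 0.803 to 0.970.

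The comparison of anti-PD1 with IgG addresses what PD-1 blockade changed in the same tumor model. In camera at the preset correlation, cell cycle genes rose and beta-catenin target genes fell as groups. A positive change of macrophage genes rested mostly on 1 library. Cell cycle genes were positive in 26 of 27 members, with a median log2 fold change of 0.39 (camera adjusted p = 5.0e-07, or adjusted p = 0.205 with an estimated correlation; fry adjusted p = 0.0095). Among them, the cyclin gene Ccna2 stood at 46.0 ± 3.75 CPM with IgG and 69.1 ± 7.19 with anti-PD1 (SD, n = 3), a change of 0.59 ± 0.17. Pcna, the replication clamp, stood at 0.77 ± 0.24 and Cdk1 at 0.71 ± 0.24, and 0 of the 27 passed over all genes tested or adjusted over the list alone. Beta-catenin target genes were negative in 10 of 12 (median -0.63; camera adjusted p = 0.0019, or adjusted p = 0.305 with an estimated correlation; fry adjusted p = 0.042), 4 of them past the threshold adjusted over the list alone. Axin2 stood at 27.2 ± 5.62 CPM with IgG and 10.2 ± 4.33 with anti-PD1, a change of -1.43 ± 0.31, and Nkd1 and Notum, which also restrain the pathway, at -2.33 ± 0.58 and -1.88 ± 0.50. Without single libraries the median ran from 0.36 to 0.42 for cell cycle and from -0.82 to -0.54 for beta-catenin target genes.

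Macrophage and monocyte genes were positive with anti-PD1 in 20 of 23 (median 0.74; camera adjusted p = 0.0070, or adjusted p = 0.917 with an estimated correlation), with the monocyte chemokine receptor Ccr2 at 2.07 ± 0.58. Fc receptor and phagocytosis genes were positive in 19 of 21 (median 0.55; camera adjusted p = 0.0052, or adjusted p = 0.851 with an estimated correlation). Macrophage levels relative to all libraries were 0.98 in anti-PD1 replicate 2, -0.16 and -0.35 in the other anti-PD1 libraries and -0.28, -0.49 and -0.75 with IgG. The medians ran from 0.20 to 1.03 for macrophage and from 0.19 to 0.81 for Fc receptor genes without single libraries. Both calls ended without IgG replicate 3 (adjusted p = 0.136 and 0.101), without anti-PD1 replicate 2 (0.465 and 0.099) and with the receptor signal as a covariate (0.816 and 0.218). Keratinocyte genes were negative in 5 of 5 (median -1.66; camera adjusted p = 0.0017, or adjusted p = 0.205 with an estimated correlation; fry adjusted p = 0.011) and erythroid genes in 5 of 6 (median -2.30; camera adjusted p = 0.0017, or adjusted p = 0.422 with an estimated correlation). Immediate early and stress genes were negative in 13 of 15 (median -0.55; camera adjusted p = 0.0037, or adjusted p = 0.629 with an estimated correlation), with Nr4a1 at -0.92 ± 0.28, and had an adjusted p of 0.057 without IgG replicate 1. Mitochondrially encoded genes were negative in 11 of 13 (median -0.72; camera adjusted p = 0.0027, or adjusted p = 0.851 with an estimated correlation) and had 0.640 without IgG replicate 3 and 0.112 with the receptor covariate. Their share of reads outside the satellite genes was 2.38% ± 0.827 with IgG and 2.40% ± 0.217 with anti-PD1 (SD, n = 3), so the total was not lower. Only 5 of 20 listed keratinocyte genes and 6 of 10 listed erythroid genes were tested. Leaving out single libraries gave medians from -2.86 to -1.28 for keratinocyte, -2.73 to -1.50 for erythroid, -0.69 to -0.41 for immediate early and -0.97 to -0.01 for mitochondrial genes. Scaled by library totals, the medians of these 4 lists and of the beta-catenin list are positive, at 1.61, 1.04, 2.56, 2.59 and 2.55, while the median of all genes is 3.15. Schwann cell genes passed only in fry (adjusted p = 0.018; median -0.73). The other 22 lists did not pass camera, with adjusted p-values from 0.059 to 0.997.

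With anti-PD1, 1 gene was higher and 50 were lower than with IgG in edgeR's quasi-likelihood test, against 995 and 1406 at an unadjusted p under 0.05. Fstl1, a secreted follistatin-like glycoprotein (ENSMUSG00000022816, chromosome 16, 37776873 to 37836514), rose from 113.9 ± 10.4 to 225 ± 26.1 CPM, a change of 0.98 ± 0.18 (edgeR adjusted p = 0.048). Its call held in 10 of 27 alternatives, where its adjusted p ranged from 3.0e-13 to 0.904. Ptger1, a prostaglandin E receptor (ENSMUSG00000019464, chromosome 8, 83666678 to 83672753), fell from 9.49 ± 2.91 to 0.275 ± 0.0163 CPM, and Cnbd2 (ENSMUSG00000038085, chromosome 2, 156312299 to 156375638) from 84.3 ± 15.8 to 4.27 ± 1.27 CPM. Their changes of -5.11 ± 0.37 and -4.30 ± 0.31 both had an edgeR adjusted p of 6.6e-05. Lower too were Gm5148 at -6.75 ± 0.47, 1810049J17Rik at -6.25 ± 0.49, Gm9573 at -7.07 ± 0.99, Muc5b at -5.82 ± 0.91, Muc4 at -5.29 ± 0.87 and Slc24a5 at -6.32 ± 0.85 (edgeR adjusted p between 6.6e-05 and 0.041). The calls of Gm5148, 1810049J17Rik and Slc24a5 held in 27, 26 and 23 of 27 alternatives. Those of Gm9573, Muc5b and Muc4 held in 17 of 27, 16 of 25 and 13 of 26. IgG reads of Muc5b and Muc4 were 0.99 and 1.36 times what the receptor background predicts. Gm5591, Tlcd2 and the satellite gene Gm17535 fell, with changes of -4.37 ± 0.79, -3.63 ± 0.54 and -4.96 ± 0.92 (edgeR adjusted p between 0.039 and 0.049), calls that held in 11 of 27, 17 of 27 and 10 of 21 alternatives. Gm26566 had 168 reads with IgG and 2 with anti-PD1, a 322-fold lower level with a counting interval of 87.9 to 2680 (edgeR adjusted p = 0.0012). The 50 became 9, 412 and 20 without IgG replicate 1, 2 or 3, 10, 12 and 10 without anti-PD1 replicate 1, 2 or 3, and 125 and 29 without anti-B7-H3 replicate 1 or 2. With the receptor signal as a covariate they became 6, and the median change of the 49 lower genes outside the satellites went from -3.15 to -1.93 and its median SE from 0.465 to 0.679.

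The direct comparison of anti-B7-H3 with anti-PD1 asks where the 2 treatments differ. The IgG libraries enter it only through the choice of tested genes and the estimates of scale and spread. In camera at the preset correlation, interferon response, antigen presentation and T cell genes were higher as groups with anti-B7-H3, and cell cycle genes were lower. Across genes, changes here ran with GC content at rho = 0.365, against -0.105 and -0.327 for anti-B7-H3 and anti-PD1 against IgG. GC content offsets, added after seeing the data, left 14 lists past the threshold against 15. The beta-catenin and mitochondrial lists lost their calls there. With an estimated correlation 0 lists passed. Interferon gamma response genes were positive in 20 of 20 members with a median log2 fold change of 1.20 (camera adjusted p = 2.8e-07, or adjusted p = 0.583 with an estimated correlation). Socs1, a feedback inhibitor of cytokine signalling, stood at 1.24 ± 0.36 and the chemokine gene Cxcl10 at 1.35 ± 0.61. MHC class I presentation genes were positive in 18 of 18 (median 0.80; camera adjusted p = 1.9e-05, or adjusted p = 0.583 with an estimated correlation), with H2-Q6 at 1.27 ± 0.48 and the peptide transporter gene Tap1 at 1.08 ± 0.56. Type I interferon genes were positive in 24 of 24 (median 0.60; camera adjusted p = 1.4e-05, or adjusted p = 0.583 with an estimated correlation). Genes of CD8 T cells and cytotoxic effectors were positive in 16 of 17 (median 0.67; camera adjusted p = 1.6e-04, or adjusted p = 0.583 with an estimated correlation), 1 of them past the threshold adjusted over the list alone, with the perforin gene Prf1 at 1.95 ± 0.50. T cell genes were positive in 17 of 19 (median 0.52; camera adjusted p = 4.7e-04, or adjusted p = 0.583 with an estimated correlation). Cell cycle genes were negative in 26 of 27 (median -0.26; camera adjusted p = 1.3e-06, or adjusted p = 0.354 with an estimated correlation), with Ccna2 at -0.53 ± 0.17 and Ccnb2 at -0.51 ± 0.18. Without single libraries the medians ran from 0.82 to 1.55 for interferon gamma, 0.59 to 1.12 for MHC class I, 0.15 to 0.96 for type I interferon, 0.32 to 0.98 for CD8, 0.33 to 0.78 for T cell and -0.32 to -0.22 for cell cycle genes. Anti-B7-H3 replicate 1 lay among the anti-PD1 libraries, with levels relative to all libraries of -0.49 against 1.19 and 1.41 in the other anti-B7-H3 libraries for interferon gamma, -0.04 against 0.92 and 0.78 for MHC class I, and -0.21 against 0.57 and 1.10 for CD8 genes.

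Among the other lists higher with anti-B7-H3 than with anti-PD1, T cell inhibitory receptors had 10 of 11 members positive (median 0.60; camera adjusted p = 8.7e-04, or adjusted p = 0.467 with an estimated correlation), with Lag3 at 1.10 ± 0.35. Checkpoint ligands had 13 of 14 (median 0.42; camera adjusted p = 7.6e-04, or adjusted p = 0.467 with an estimated correlation). Immediate early and stress genes had 14 of 15 positive (median 0.56; camera adjusted p = 1.3e-05, or adjusted p = 0.467 with an estimated correlation), and hypoxia and glycolysis genes 20 of 21 (median 0.38; camera adjusted p = 1.8e-04, or adjusted p = 0.583 with an estimated correlation), with the glucose transporter gene Slc2a1 at 1.09 ± 0.39. MHC class II genes had 9 of 10 (median 0.65; camera adjusted p = 0.0013, or adjusted p = 0.583 with an estimated correlation), Fc receptor genes 18 of 21 (median 0.29; camera adjusted p = 0.0019, or adjusted p = 0.583 with an estimated correlation) and beta-catenin targets 10 of 12 (median 0.25; camera adjusted p = 0.035, or adjusted p = 0.583 with an estimated correlation). Mitochondrially encoded genes were negative in 13 of 13 (median -0.38; camera adjusted p = 0.024, or adjusted p = 0.721 with an estimated correlation). Skeletal muscle genes were called lower by camera (adjusted p = 0.0038; adjusted p = 0.721 with an estimated correlation), although 16 of 20 members and the median of 0.32 were positive, and without anti-B7-H3 replicate 2 the list was called higher with a median of 0.91. Leaving out single libraries gave medians from 0.30 to 1.06 for inhibitory receptors, 0.34 to 0.49 for checkpoint ligands, 0.38 to 0.70 for immediate early, 0.22 to 0.53 for hypoxia, 0.36 to 0.98 for MHC class II, 0.12 to 0.62 for Fc receptor, 0.10 to 0.29 for beta-catenin target and -0.58 to -0.20 for mitochondrial genes. The other 15 lists did not pass, with camera adjusted p-values from 0.063 to 0.928. Without anti-B7-H3 replicate 3 the camera adjusted p-values of the Fc receptor, MHC class II, mitochondrial and beta-catenin lists were 0.239, 0.063, 0.283 and 0.118, and without anti-B7-H3 replicate 2 the type I interferon list had 0.119 and the beta-catenin list 0.080. Without anti-PD1 replicate 1 the MHC class II and mitochondrial lists had 0.074 and 0.255, without anti-PD1 replicate 2 the muscle and beta-catenin lists had 0.209 and 0.432, without anti-PD1 replicate 3 the Fc receptor, mitochondrial and beta-catenin lists had 0.095, 0.076 and 0.078, and without IgG replicate 1 or 2 the beta-catenin list had 0.063 and 0.070.

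No single gene passed the threshold between anti-B7-H3 and anti-PD1: edgeR called 0 higher and 0 lower, against 508 and 332 at an unadjusted p under 0.05. DESeq2 called 11 and 13, and limma-voom 0 and 0. The smallest adjusted p in edgeR, 0.146, belonged to Atg9b, an autophagy gene, at 2.20 ± 0.31, and to Ptn, the growth factor pleiotrophin, at -1.52 ± 0.22. Atg9b had 7.79 ± 1.79 CPM with anti-B7-H3 and 1.70 ± 0.431 with anti-PD1 (SD, n = 3), and Ptn had 22.98 ± 5.19 and 65.8 ± 12.8. The other 8 genes with the smallest p did not pass either. They were Igsf9b at 2.25 ± 0.37, Gm15128 at 2.05 ± 0.41, Crmp1 at 1.84 ± 0.36, Klhl21 at 1.32 ± 0.25, Slc9a2 at 1.18 ± 0.24, Lrrc17 at -1.23 ± 0.25, Rpl10 at -1.62 ± 0.26 and Arl5b at -2.87 ± 0.51.

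**Figure D2:**
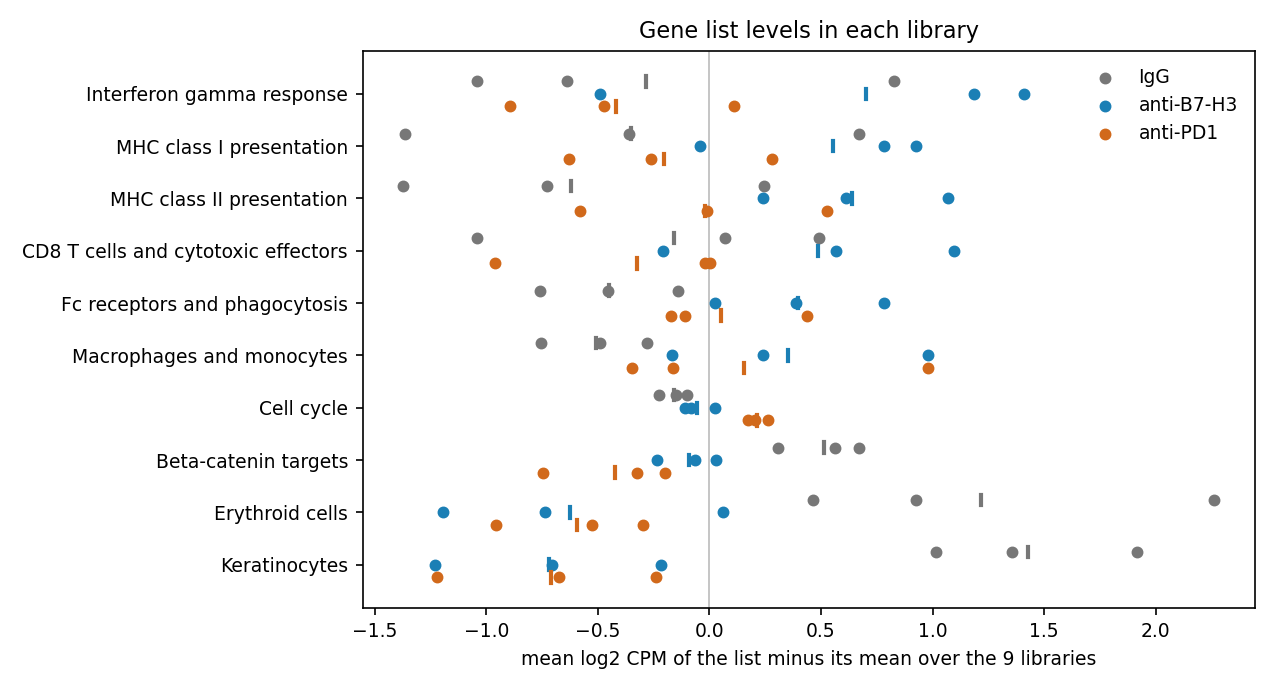
Levels of 10 gene lists in each library, as the mean log2 CPM of the list minus its mean over the 9 libraries. Each point is a library, coloured by group, and each bar a group mean. Cell cycle levels of the 3 anti-PD1 libraries, 0.18 to 0.26, lie above those of the other 6. Anti-B7-H3 replicate 1 lies at -0.49 for interferon gamma response, apart from the 1.19 and 1.41 of the other 2.

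Across all 3 groups, 148 of 12965 genes differed in edgeR's quasi-likelihood test, and 1813 had an unadjusted p under 0.05. The number became 11, 426 and 26 without IgG replicate 1, 2 or 3, 259, 56 and 44 without anti-B7-H3 replicate 1, 2 or 3, and 30 and 31 without anti-PD1 replicate 2 or 3. With the receptor signal as a covariate it was 0.

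Of the genes lower than IgG, 29 were lower with both, among them Gm5148, 1810049J17Rik, Gm26566, Gm9573, Muc4, Muc5b and Slc24a5, and 0 were higher with both. Simulations of unchanged groups against the same controls gave 0 lower with both at most, and lists drawn independently would share 0.274. These simulations hold chance alone and not the background that the IgG libraries share, and with the receptor signal as a covariate the 29 became 0. Across genes, which are not independent replicates, the log2 fold changes of the 2 antibodies had a correlation of 0.873 against a simulated mean of 0.610. Their covariance was 0.755 against 0.156, a difference of 0.599. The 29 became 7, 334 and 13 without IgG replicate 1, 2 or 3, 81, 11 and 10 without anti-B7-H3 replicate 1, 2 or 3, and 10, 12 and 10 without anti-PD1 replicate 1, 2 or 3.

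None of the genes of the antibody targets and of the series title passed the threshold in edgeR. Cd276 had 6.56 ± 1.36 CPM with IgG, 7.58 ± 1.61 with anti-B7-H3 and 5.65 ± 1.24 with anti-PD1 (SD, n = 3). Pdcd1 had 1.17 ± 0.874, 2.44 ± 1.25 and 0.977 ± 0.169 CPM. Cd274, the gene of the PD-1 ligand PD-L1, had 6.27 ± 5.28, 14.4 ± 9.71 and 4.14 ± 1.68 CPM, and anti-B7-H3 stood 1.81 ± 0.68 above anti-PD1 (edgeR adjusted p = 0.749). The second ligand gene, Pdcd1lg2, stood 1.37 ± 0.58 above. Cd47, the gene of a signal that inhibits phagocytosis, had 25.8 ± 3.65, 39.8 ± 6.77 and 39.3 ± 1.56 CPM, and all 6 antibody libraries lay above all 3 IgG libraries. Its changes against IgG were 0.61 ± 0.18 with anti-B7-H3 and 0.59 ± 0.18 with anti-PD1 (edgeR adjusted p = 0.191 and 0.138). Sirpa, the gene of the CD47 receptor on myeloid cells, stood at 0.81 ± 0.29 and 0.78 ± 0.29. Ctnnb1, the gene of beta-catenin, had 216 ± 33.7, 259 ± 17.2 and 296 ± 33.4 CPM.

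**Figure D3:**
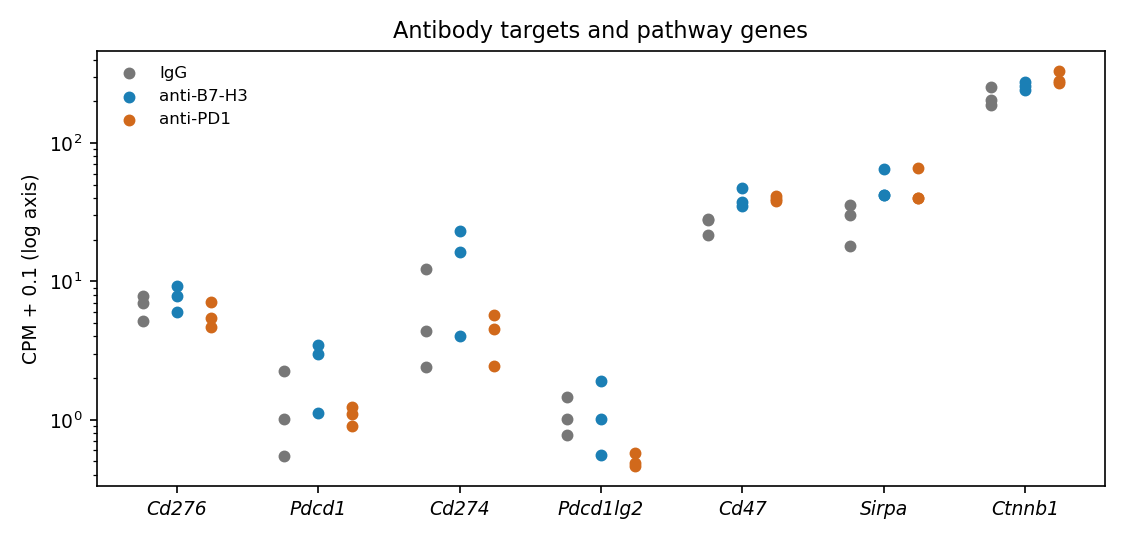
Levels of 7 target and pathway genes in each library, as CPM plus 0.1 on a log axis. Points are libraries, coloured by group. Cd47 lies at 21.6 to 28.0 CPM with IgG and at 34.9 to 47.5 CPM in the antibody libraries, and Cd274 spans 2.30 to 23.1 CPM over all libraries.

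None of the marker genes of the immune subsets that the series names passed the threshold in edgeR. With IgG, anti-B7-H3 and anti-PD1, the CD8 T cell gene Cd8a had 2.02 ± 2.13, 3.45 ± 1.57 and 1.67 ± 0.761 CPM (SD, n = 3), and Cd4 had 1.42 ± 1.22, 1.58 ± 0.390 and 2.14 ± 0.466 CPM. The granzyme gene Gzmb had 2.03 ± 1.25, 4.10 ± 2.16 and 1.24 ± 0.216 CPM, and Ifng, the gene of interferon gamma, 0.260 ± 0.450, 0.479 ± 0.156 and 0.132 ± 0.0903 CPM. Itgax, a dendritic cell and macrophage integrin, had 14.6 ± 5.75, 32.5 ± 15.5 and 11.3 ± 2.94 CPM, and the macrophage gene Adgre1 had 19.4 ± 7.52, 54.8 ± 24.3 and 49.5 ± 31.9 CPM. The natural killer cell gene Ncr1 and the regulatory T cell gene Foxp3 stayed under 0.8 CPM on average in every group. Cdkn2a, deleted in the YUMM parent line, had 3.07 ± 0.739 CPM with IgG. Braf had 13.4 ± 2.53, 12.02 ± 1.45 and 12.9 ± 5.14 CPM.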

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

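The alternatives with GC content offsets, satellite genes removed, background subtracted, receptor signal as a covariate, equal depth, and the further left-out libraries were chosen after seeing the data, and the others before. Of 5140 changes of single genes under an alternative, 4674 stayed on their side of the threshold, 138 of them with the opposite sign and past it in neither fit, 218 fell short of it, 216 newly passed it and 32 passed it with the opposite sign. Of 985 list values, 874 kept their direction and call, 106 lost the call and 5 were reversed. With the preset correlation, lists called the same way in 25 of 25 alternatives were cell cycle with anti-PD1 against IgG, and interferon gamma, MHC class I, checkpoint ligand, hypoxia, immediate early and cell cycle genes between the antibodies. Keratinocyte and erythroid lists against IgG, and CD8 and inhibitory receptor lists between the antibodies, also kept their calls in all 23 or 24 alternatives that gave a value. Depth limits the IgG libraries most, since as few as 1218985 reads lay outside the satellite genes there. Unless a sentence says otherwise, the cause of a difference was not tested. Counts below are given as genes higher and lower, and the overlap is the number of genes called the same way against IgG with both antibodies.

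Camera with an estimated correlation called 0, 0 and 0 lists for anti-B7-H3 against IgG, anti-PD1 against IgG and anti-B7-H3 against anti-PD1, and fry called 1, 4 and 0. DESeq2 called 26 higher and 470 lower with anti-B7-H3, 179 and 635 with anti-PD1, 11 and 13 between the antibodies, 771 among the 3 groups and an overlap of 394. With limma-voom the counts were 0 and 45, 2 and 32, and 30 among the 3 groups. Quality weights gave 14 and 340, 152 and 280, 1 lower between the antibodies, 260 among the 3 groups and an overlap of 173. Without a filter on low counts, 131 and 966 genes were called with anti-B7-H3, 270 and 461 with anti-PD1, 2 and 2 between the antibodies, 1683 among the groups and an overlap of 386. A minimum of 1 CPM in 3 libraries gave 0 and 10, 0 and 16, 74 among the groups and an overlap of 8. Fits of only the 6 libraries compared gave 0 and 20 with anti-B7-H3, and 2 and 86 with anti-PD1. Effective length offsets gave 8 higher with anti-B7-H3, and 4 and 23 with anti-PD1. A threshold of 0.01 gave 0 and 10, 0 and 9, 14 among the groups and an overlap of 8, and a minimum fold of 1.5 gave 0 and 22, 0 and 15 and an overlap of 12, both being stricter by construction.

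With replicate number as a block, 0 genes were higher and 124 lower with anti-PD1, and the overlap was 73, while the other counts stayed within 1.5 times. Correlations showed no pairing by number: 2 of 9 libraries correlated best with a library of their own number. The same-number correlations ran from -0.324 to 0.18. With 3 libraries per group this cannot show that the numbers share nothing. Replicate 1 had the highest satellite share of each group, at 92.1, 28.2 and 38.2% with IgG, anti-B7-H3 and anti-PD1.

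Library totals, which put the median of all genes at 3.37 and 3.15 against IgG, called 12456 genes higher with anti-B7-H3, 12287 with anti-PD1, 21 higher and 2 lower between the antibodies, 12398 among the groups, an overlap of 12281, and 8 and 13 lists against IgG. By this construction 32 negative changes against IgG passed the threshold as positive. With anti-B7-H3 they were Bcl11b 1.19, Axin2 2.15, Hbb-bt 1.32, Nr4a1 2.80, mt-Nd2 1.29, Braf 3.18, Foxp3 2.93 and Ncr1 2.40. With anti-PD1 they were Lag3 2.32, H2-Q6 2.46, Socs1 1.87, Oasl1 2.41, Axin2 1.65, Notum 1.34, Ankrd37 2.21, Slc2a1 2.12, Hbb-bt 1.12, Nr4a1 2.28, Socs3 2.56, Ier3 1.65, mt-Nd2 1.56, Cd274 2.57, Pdcd1lg2 1.94, Pdcd1 3.03, Cd276 2.90, Braf 3.03, Gzmb 2.69, Itgax 2.83, Foxp3 2.67, Cd8a 2.99, Ifng 2.21 and Ncr1 2.39. The CD8 list with anti-B7-H3, at a median of 4.27, was called lower relative to the other genes.

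GC content offsets gave 0 and 28 genes with anti-B7-H3, 0 and 18 with anti-PD1, 92 among the groups and an overlap of 13, while the median change of the lower genes outside the satellites was -4.72 against -4.71 with anti-B7-H3 and -3.03 against -3.15 with anti-PD1. Without the satellite genes the counts were 5 and 477, 32 and 279, 545 and an overlap of 221. Subtracting the background as well gave 38 and 22 lower, 92 and an overlap of 19, with medians of -5.08 over the 48 of 60 lower genes still tested and -2.71 over 47 of 49. The receptor covariate left 0 and 0 with anti-B7-H3, 6 lower with anti-PD1, 0 among the groups, an overlap of 0 and 6 lists for anti-B7-H3 against IgG, and it turned the medians of MHC class I, cytokine and hypoxia genes to -1.02, -0.79 and -0.59. Thinning to equal depth, which removes reads, gave 0 and 3, 0 and 6, 15 and an overlap of 3. Without both antibody replicates 1, and without satellite genes, 19 and 228 genes were called with anti-B7-H3, 449 among the groups, an overlap of 54 and 14 lists for anti-PD1. Without IgG replicate 3 and satellite genes the counts were 0 and 25, 0 and 20, 37, an overlap of 12 and 5 lists for anti-PD1.

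Leaving out each library in turn gave 0 to 13 genes higher and 8 to 432 lower with anti-B7-H3, 0 to 20 higher and 9 to 412 lower with anti-PD1, and 0 and 0 between the antibodies. It gave 11 to 426 genes among the groups, an overlap of 7 to 334, and 12 to 20, 5 to 12 and 11 to 19 lists in the 3 comparisons. A group left with 2 libraries was tested against the pooled spread. Between the antibodies, the skeletal muscle list turned to a median of 0.908 and was called higher without anti-B7-H3 replicate 2, and its medians without single libraries ran from -1.94 to 1.33.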

Other observations

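The tests of explanations in this part were chosen after the results were seen, while the tests of lists and genes against the main threshold and the counts of other splits were planned, the bounds for these counts being written down afterwards.

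Skeletal muscle genes were at very different levels in single libraries: their mean log2 CPM relative to all 9 libraries was -4.74 in anti-B7-H3 replicate 2, 3.53 in replicate 3 and 1.16 in replicate 1, 2.90 in anti-PD1 replicate 2, and between -1.55 and -0.91 with IgG. The actin gene of skeletal muscle, Acta1, had 0.111 CPM in anti-B7-H3 replicate 2 and 392 CPM in replicate 3. Igkc, the antibody light chain gene of plasma cells, stood at 2.83 ± 1.02 (SE) with anti-PD1 against IgG, and at 24.0 CPM in anti-PD1 replicate 2 alone against 2.77 and 6.28 in the other 2. The fibroblast and matrix list did not pass camera with anti-PD1 against IgG (adjusted p = 0.087), with 11 members positive, 9 negative and a median of 0.05. Its 4 members with the smallest p were Postn at 1.30 ± 0.26, Fap at 1.64 ± 0.41, Acta2 at 0.98 ± 0.28 and Lum at 1.41 ± 0.50. The first 3 of these were the members past the threshold adjusted over the list alone, and 0 passed over all genes tested. Anti-B7-H3 against anti-PD1 gave -0.78 ± 0.25 for Postn, -1.14 ± 0.34 for Fap and -1.35 ± 0.48 for Lum. In the T cell and CD8 lists, the transcription factor genes Bcl11b and Eomes stood at -2.41 ± 0.75 and -2.92 ± 0.76 with anti-B7-H3 against IgG, opposite to most members.

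In the main fit nearly all genes called were lower than in the IgG libraries, where satellite reads and receptor background were also higher. Fewer reads outside the satellites in the IgG libraries stay open as a cause. Thinning to equal depth cannot decide this, because it keeps each gene's share of reads on average, so folds of genes already called could hardly move. After thinning, the median change of the genes lower with anti-B7-H3 was -4.443 against -4.71 before, with 35 of the 60 outside the satellites still tested. Only 3 were still called, as the median SE went from 0.803 to 1.07. An even background over coding sequence cannot be told apart from other causes: reads of the 81 called genes in IgG were a median of 8.779 times what the receptor genes predict, and 68 lay above the 99th percentile of the receptor genes, but 20 lay under 3 times, and the genes were picked for high IgG reads. With this background subtracted, the median change of the genes lower with anti-B7-H3 was -5.08 against -4.71 before. All 48 still tested were negative and 25 were still called, yet 12 of the 60 were no longer tested. Genes with 1 coding exon made up 15 of the 60 lower genes with anti-B7-H3 and 17 of 49 with anti-PD1. Among tested genes outside the satellites they made up 5.69%, and the cause of this excess was not tested. A background that varies whatever the antibody also stays open, because over the 6 antibody libraries the level of the called genes and the satellite share had r = 0.752 (exact permutation p = 0.101, adjusted p = 0.101 over 2 relations; rho = 0.6, p = 0.242; r = 0.744 without the 2 outermost libraries), too few libraries to decide. A difference in tissue or treatment between IgG and antibody tumors is untested and confounded with these measures.

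Interferon gamma response genes were higher with anti-B7-H3 than with anti-PD1. Unequal background stays open as a cause. With the receptor signal as a covariate the median stayed at 0.838 against 1.20 (camera adjusted p = 1.9e-05 at the preset correlation). In the main fit, camera with an estimated correlation had an adjusted p of 0.583. The covariate fit takes 1 slope over all 9 libraries, IgG included, so it cannot decide for the 6 antibody libraries. Background reads themselves were few there, at most an estimated 0.617% of other reads. Over these 6 libraries the level of the list and the satellite share had a negative relation (r = -0.904, exact permutation p = 0.028, adjusted p = 0.056, and rho = -0.714 with p = 0.136). Without the 2 libraries outermost in satellite share, anti-B7-H3 replicates 2 and 3, r was -0.404. These 2 also hold the highest list levels, 1.19 and 1.41. Leaving them out therefore cannot tell a link to satellite share from a difference between the antibodies. The spread between single tumors cannot be told apart from the antibody, because the list levels gave an exact 2-sided permutation p of 0.3 where 3 against 3 cannot go below 0.1, and anti-B7-H3 replicate 1, at -0.49, lay among the anti-PD1 libraries. A difference in the interferon response of the tumors may exist, and remains a hypothesis.

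Cell cycle genes were higher with anti-PD1 than with IgG. A GC content trend runs across genes at rho = -0.327 in this comparison. This trend is argued against as the whole cause, since the median was 0.324 with GC content offsets against 0.39 before. The list stayed called there and in all 25 alternatives, the receptor covariate among them. Over these alternatives its median went as low as 0.187, against 0.39 in the main fit. Beyond the receptor covariate, the background that sets the IgG libraries apart was not tested as a cause. It separates IgG from the antibody libraries, so it stays confounded with this comparison. The spread between single tumors cannot be told apart from the antibody, because the tests that allow for correlation between members part: fry passed (adjusted p = 0.0095), and camera with an estimated correlation did not (adjusted p = 0.205). Against a chance spread stand the levels of -0.16 (SD 0.06) with IgG and 0.21 (SD 0.05) with anti-PD1, and medians of 0.36 to 0.42 without single libraries. The 3 anti-PD1 libraries lay above the other 6, with an exact 2-sided permutation p of 0.0119, the smallest that 84 splits can give, which for 1 of 30 lists decides nothing after adjustment. More dividing cells with anti-PD1 is a candidate explanation that was not tested further.

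Other splits of the same libraries were counted for each number of calls. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 split gave at least the 72 called with anti-B7-H3 against IgG (highest other 0), 1 gave the 51 with anti-PD1 against IgG (highest other 0), and all 10 gave the 0 between the antibodies (highest other 0). For lists, 1 split gave the 17 with anti-B7-H3 against IgG (highest other 16), 6 gave the 8 with anti-PD1 against IgG (highest other 19) and 4 gave the 15 between the antibodies (highest other 17). Among 100 splits of the 9 libraries into 3 groups, 1 gave the 148 genes that differed among the groups, the real one. A random split would thus rarely give as many. The highest other gave 114: the 3 other splits that keep the IgG libraries together gave 66 to 114, and the 96 that part them gave at most 2. The count thus reflects mainly IgG against the rest. Only 3 other splits kept the IgG libraries together, too few to decide whether the real grouping exceeds such splits.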
